A study of Mus musculus with 30 samples.

How the data were processed

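Gene expression was measured by RNA sequencing in cultures of primary mouse microglia, the resident macrophages of the brain, from wild-type (WT) mice and mice labelled PD-1 KO. PD-1 is an inhibitory receptor encoded by Pdcd1. The labels give 10 groups of 3 libraries, 30 in all: both genotypes at 0 h, and at 2 h and 8 h with and without amyloid-beta, which was given as conditioned medium. The labels do not state which medium the untreated cultures received, or whether the 3 libraries of a group come from different animals, so p-values measure the spread between these libraries.

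The deposited file holds 1 signal value per gene and library, for 13788 genes. Each of them reaches at least 12.2 in some library, so genes low in every library are not in it. The absence of a gene therefore does not show that it had no reads. Its values are gene counts that the authors divided by a size factor per library and floored at 1, as the values themselves show: none is below 1, and above the floor each library's values are whole multiples of 1 step. The submitters' processing notes name HISAT 0.1.5, Partek 6.6, R 3.0.2, DESeq2 without a version and the mm10 genome build, and give no role for each. The counting program and the annotation are not stated.

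Dividing each library's values by its step gave the reads behind them. All values of up to 5000 reads were whole within a tolerance of 0.05 in every library (100.0%). The recovered totals, over the genes in the file only, ran from 4227019 to 48509985 reads per library, with a median of 9603082. A total of 4485 values (1.08%) lay at the floor, which can hide up to 4 reads in 12 of the libraries. For that reason the values were tested on the log2 scale and no count model was fitted. Where a gene lay at the floor in a whole group, its limit was set at 3 reads, which covers counting error only.

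Values were analysed as log2 of the value plus 1. A gene was tested when its value reached 10 in at least 3 of the 30 libraries, which left 13722 genes. One mean per group was fitted to all 30 libraries with limma 3.58.1 in R 4.3.3, using its moderated test with an intensity trend, with 20 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. There were 15 comparisons: amyloid-beta against none in each genotype at 2 h and 8 h, the genotype difference of that effect at each time, its difference between the times, PD-1 KO against WT in each of 5 conditions and over all of them, and 2 h and 8 h against 0 h without amyloid-beta. The fit, the filter, the comparisons, the gene lists and the rule for named genes were chosen before the data were examined.

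The rule named, for each comparison, up to 8 increases and 8 decreases with the largest fold among genes past the threshold with a mean in the upper part of the tested genes and no overlap between the groups, up to 4 members of each gene list, and a fixed set of genes of interest. Genotype differences and averages had no overlap condition. The text gives part of the genes that the rule named.

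Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Of 26 lists, 25 had at least 3 tested genes. The list of neutrophil, lymphocyte and red cell markers had 0 of its 13 genes in the file and was not tested. Il6, Nos2, Arg1 and Il10 are not in the file and were not analysed here. Members past the threshold were counted both over all genes tested and adjusted over the list alone. Pdcd1 was compared between the genotypes by a two-sided permutation test with 100000 resamples.

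The same steps were tested on simulated data for amyloid-beta against none in WT at 8 h, with known changes in 199 of 13598 genes. They recovered 75 of 99 changes of 2-fold and 90 of 100 changes of 4-fold, with 8 false calls among 173. These shares hold for the simulated data only and do not give the error rate of the real calls. The real count in this comparison, 299 genes, ran from 55 to 513 when libraries were left out in turn.

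The alternatives were other pseudocounts (0 and 10), no low-value filter or a filter at 50, quantile normalization, TMM factors, a fit with only the groups compared, limma without trend, robust empirical Bayes, array weights, a fold minimum, and leaving out each library. Added after the data were seen were voom on the recovered reads, leaving out a pair of libraries together, and a score of astrocyte markers as covariate. Gene positions came from the GRCm38 annotation, which placed 13677 genes (99.2%), 415 of them through an older symbol. Figures were drawn with matplotlib 3.10.9.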

Results

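RNA was sequenced from 30 microglia cultures in 10 groups of 3 libraries: WT and PD-1 KO at 0 h, and each genotype at 2 h and 8 h without and with amyloid-beta medium. Depth ran from 4227019 to 48509985 reads per library, with medians of 9763779 reads in the 15 libraries labelled PD-1 KO and 9442385 reads in the 15 labelled WT. Fewer genes lay at the floor in libraries labelled PD-1 KO (25 to 96 per library) than in those labelled WT (142 to 452). The 10 highest genes held 9.31% to 11.2% of the values in libraries labelled PD-1 KO and 11.7% to 14.1% in those labelled WT. All fold changes below are log2 values ± standard error from limma, and values of single genes are means ± SD of the deposited signal.

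Pdcd1, the gene targeted in the knockout (chromosome 1, 94038305 to 94052553, GRCm38), was above the floor only in libraries labelled PD-1 KO. It lay at the floor of 1 in all 15 libraries labelled WT, and at 6.02 to 25.3 in all 15 labelled PD-1 KO (mean 14.2 ± 5.95, n = 15), from 3 to 46 reads per library. The difference had p = 1e-05 in a two-sided permutation test, the smallest that 100000 resamples can give. In 11 libraries labelled WT the floor hides no read, and 3 reads over these 11 together correspond to a value of 0.368, so Pdcd1 was at least 38.5-fold higher in the libraries labelled PD-1 KO. The values are per gene, so they do not show whether the reads lie inside or outside the part that was targeted. Every direction between genotypes below is therefore given for libraries as labelled.

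**Figure D1:**
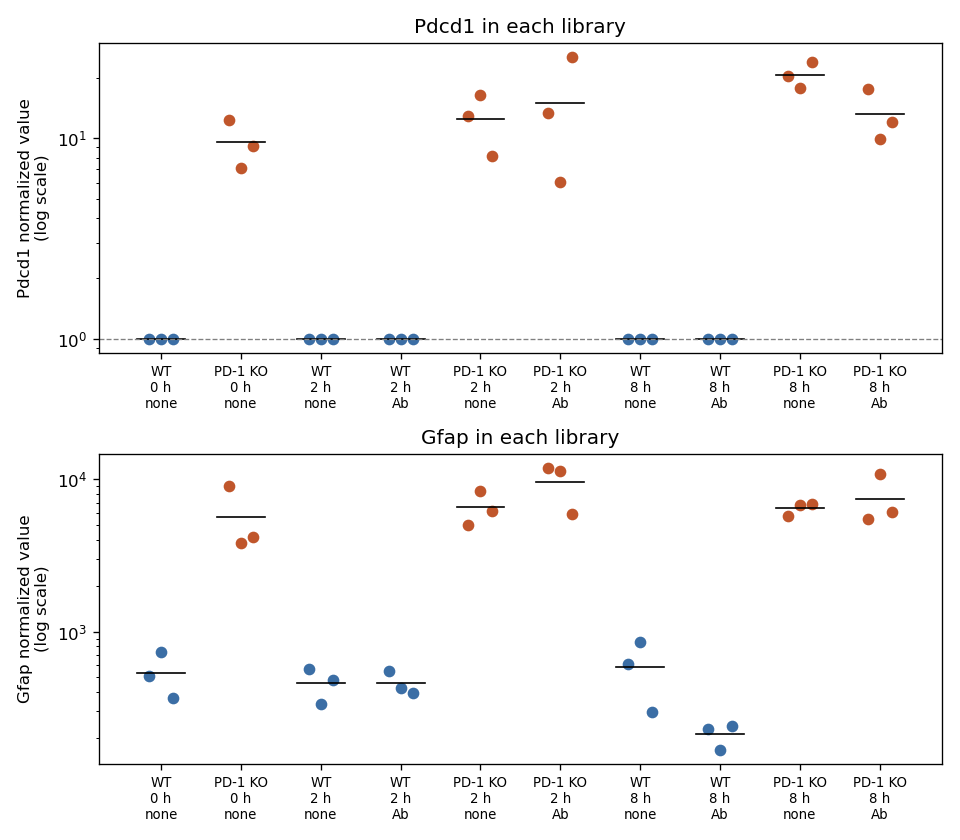
Deposited values of Pdcd1 and of the astrocyte marker Gfap on log axes; each point is 1 of 3 libraries of a group, black bars are group means, and the dashed line marks the floor of 1. Pdcd1 lies at 1 in the 15 libraries labelled WT and between 6.02 and 25.3 in the 15 labelled PD-1 KO, and Gfap lies between 168 and 853 in the former and between 3799 and 11792 in the latter.

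Libraries labelled PD-1 KO were compared with those labelled WT to ask what differs with the labelled genotype. Over all conditions, 15 libraries against 15, markers of other brain cells differed. Gfap was higher in libraries labelled PD-1 KO by 4.03 ± 0.15 (7133 ± 2538 against 451 ± 193), Gja1 by 3.64 ± 0.16 and Aqp4 by 3.45 ± 0.14. All 10 astrocyte markers passed the threshold, also when adjusted over the list alone, with a median of 2.79 (adjusted p = 0.216 with an estimated correlation). Dnah6 was higher by 5.52 ± 0.30, Rsph4a by 5.38 ± 0.27, Ctse by 4.91 ± 0.13 and Dnah9 by 4.74 ± 0.26; Dnah6 and Rsph4a lay at the floor in 1 of the 15 libraries labelled WT, which their folds depend on in part. Of 11 oligodendrocyte lineage markers 7 were higher and 3 lower, over all genes and adjusted over the list alone (adjusted p = 0.216 with an estimated correlation). Among them Mog stood at 2.75 ± 0.15 and Mag at 2.66 ± 0.11. Dcn, at the floor in 3 of 15 libraries labelled WT, was higher by 4.03 ± 0.27 (2.41 with pseudocount 10). The fibroblast and vascular markers did not pass as a list (6 of 10 higher and 2 lower, 8 and 2 adjusted over the list alone, adjusted p = 0.0982). Neuron markers went both ways (4 of 9 higher and 5 lower, also adjusted over the list alone; list adjusted p = 0.76): Stmn2 was higher by 1.36 ± 0.16 and Map2 by 0.96 ± 0.10, while Snap25 (-1.25 ± 0.21) and Gad1 (-1.02 ± 0.18) were lower. With quantile normalization Stmn2 came to 0.76, Snap25 to -2.08 and Gad1 to -1.79, and with pseudocount 10 Snap25 came to -0.80.

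Among genes of microglia, Olfml3 was lower in libraries labelled PD-1 KO by the widest margin of the named genes (-4.18 ± 0.10; 33.5 ± 8.81 against 616 ± 130, adjusted p = 6.81e-23). Cd300ld (-2.48 ± 0.07), Cd5l (-2.02 ± 0.10), Gpnmb (-1.62 ± 0.05), Fabp4 (-1.60 ± 0.07) and Fcrls (-1.46 ± 0.08) were lower as well, as were Dynlt1b (-1.88 ± 0.08), Tmem104 (-1.86 ± 0.04) and Mcm6 (-1.69 ± 0.06). Lysosome genes were lower in 27 of 28 cases and higher in 1, over all genes and adjusted over the list alone, with a median of -0.50 (adjusted p = 0.216 with an estimated correlation). Hexa stood at -0.81 ± 0.06, Psap at -0.75 ± 0.05 and Ctss at -0.72 ± 0.05; with quantile normalization they came to -0.47, -0.33 and -0.44, still past the threshold. Apoe (-0.72 ± 0.08), Cd68 (-0.64 ± 0.05), Cd36 (-0.60 ± 0.06) and Trem2 (-0.55 ± 0.07) were lower. They stayed past the threshold with quantile normalization, but at -0.26, -0.36, -0.17 and -0.25. The amyloid-degrading enzymes and lipid carriers, with 8 of 15 higher and 6 lower and a median of 0.21, did not pass as a list (adjusted p = 0.752). Nor did the LXR targets, with 5 of 12 higher and 6 lower (median -0.02, mean 0.15, adjusted p = 0.945). Both lists had the same counts adjusted over the list alone. Marco was higher by 2.42 ± 0.11 and C3 by 3.44 ± 0.10. The list of phagocytic receptors and uptake machinery had 8 members higher and 17 lower and did not pass (adjusted p = 0.12). Its median was -0.17 and its mean 0.08. The pan-microglia and macrophage list had 10 of 14 members lower and 2 higher, over all genes and adjusted over the list alone (median -0.37, adjusted p = 0.541 with an estimated correlation). These microglial differences stand beside the 10 of 10 higher astrocyte markers.

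Inflammatory genes were higher in libraries labelled PD-1 KO over all conditions: Ccl2 by 2.82 ± 0.22 (at the floor in 1 of 15 libraries labelled WT), Cxcl2 by 2.39 ± 0.15, Cxcl10 by 2.25 ± 0.12 and Il1b by 1.72 ± 0.15. Of 16 inflammatory cytokines and chemokines 12 were higher and 1 lower, over all genes and adjusted over the list alone, with a median of 0.93 (adjusted p = 0.216 with an estimated correlation). Among 20 genes of the NF-kB pathway 13 were higher and 0 lower by limma, also when adjusted over the list alone, with Traf1 at 2.88 ± 0.20 and Tnip3 at 1.83 ± 0.07 (list adjusted p = 0.322 with an estimated correlation). Interferon genes were lower in 19 of 27 cases and higher in 2, over all genes and adjusted over the list alone, with a median of -0.60 (adjusted p = 0.541 with an estimated correlation). Oas3 stood at -2.09 ± 0.23 and Zbp1 at -1.62 ± 0.14, but Gbp2 at 2.61 ± 0.10. A difference between conditions was tested only with against without amyloid-beta. For this list it passed at 2 h (adjusted p = 0.00182 with an estimated correlation) but not at 8 h (adjusted p = 0.568 with an estimated correlation). The list median was -0.21 at 0 h (2 higher, 4 lower, adjusted p = 0.288) and -0.16 at 8 h with amyloid-beta (6 higher, 6 lower, mean 0.14, adjusted p = 0.677). It was -0.50 at 2 h (2 higher, 10 lower, adjusted p = 0.659 with an estimated correlation), -1.68 at 2 h with amyloid-beta (adjusted p = 0.171 with an estimated correlation) and -0.40 at 8 h (1 higher, 11 lower, adjusted p = 0.596 with an estimated correlation). Homeostatic genes were split: Cx3cr1 (0.71 ± 0.08) was higher and Gpr34 (-1.09 ± 0.10) lower. The list had 4 members higher and 7 lower, over all genes and adjusted over the list alone, and a median of -0.14 (adjusted p = 0.541 with an estimated correlation). P2ry12 (0.24 ± 0.09) and Tmem119 (0.45 ± 0.12) were higher with the authors' scaling, but with quantile normalization they turned to -0.15 and -0.16 and did not pass. The checkpoint ligands Cd274 (-0.16 ± 0.06) and Lgals9 (-1.10 ± 0.07) were lower. Astrocyte markers were higher in all of these comparisons.

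At 0 h, with 3 libraries against 3, 1896 genes were higher and 944 lower in libraries labelled PD-1 KO. Cxcl10 was higher by 3.35 ± 0.26 (158 ± 9.74 against 14.8 ± 3.46) and Il1b by 3.44 ± 0.33. The cytokine list passed with an estimated correlation (9 of 16 higher, 9 higher and 1 lower adjusted over the list alone, median 1.04, adjusted p = 0.0234 with an estimated correlation). So did the receptors of motility, with 9 of 11 higher and 1 lower (9 and 2 adjusted over the list alone), a median of 0.90 and Cx3cr1 at 2.00 ± 0.19 (adjusted p = 0.0234 with an estimated correlation). The motility list did not pass at 2 h (median 0.14, adjusted p = 0.508), 2 h with amyloid-beta (median -0.10, mean 0.06, adjusted p = 0.651), 8 h (0.11, adjusted p = 0.372) or 8 h with amyloid-beta (0.25, adjusted p = 0.456), and Cx3cr1 did not pass at 2 h (0.14, adjusted p = 0.614). Gfap was higher by 3.33 ± 0.34 in the same libraries. Il1b did not pass at 2 h (0.57 ± 0.33, adjusted p = 0.197; it passed without replicate 1 of WT 2 h) or at 2 h with amyloid-beta (0.03 ± 0.33, adjusted p = 0.952), and was higher at 8 h by 2.05 ± 0.33 and at 8 h with amyloid-beta by 2.52 ± 0.33. At 2 h with amyloid-beta, interferon genes were lower in 22 of 27 cases and higher in 2, over all genes and adjusted over the list alone (median -1.68, adjusted p = 0.171 with an estimated correlation). Oas3 stood at -5.47 ± 0.52, Mx1 at -4.12 ± 0.41, Zbp1 at -3.54 ± 0.32 and Irf7 at -3.03 ± 0.25; Oas3 lay at the floor in 1 of the 3 libraries labelled PD-1 KO, so its fold depends in part on the floor. At 8 h with amyloid-beta, the oligodendrocyte list passed with an estimated correlation (10 of 11 higher, also adjusted over the list alone; median 1.20, adjusted p = 0.0361 with an estimated correlation).

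Over the genome the calls were 4163 higher and 3995 lower over all conditions (51.0% higher; 34.2% with quantile normalization), and at 0 h 66.8% were higher (51.3% with quantile normalization). At 2 h, 2580 were higher and 1832 lower (58.5%; 42.3% with quantile normalization), and with amyloid-beta 3051 and 2290 (57.1%; 40.4% with quantile normalization). At 8 h, 2471 were higher and 1237 lower (66.6%; 46.0% with quantile normalization), and with amyloid-beta 3023 and 1603 (65.3%; 40.9% with quantile normalization). Quantile normalization placed the median of all genes at -0.11 over all conditions, against -0.02 with the authors' scaling.

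Amyloid-beta at 2 h was compared with none in each genotype to ask for an early response. In WT, the interferon genes rose as a list: 27 of 27 members were higher, with a median of 0.69 (adjusted p = 0.00884 with an estimated correlation). Bst2 stood at 0.40 ± 0.18 (2311 ± 98.7 against 1792 ± 458, n = 3) and did not pass as a single gene (adjusted p = 0.981). None of the interferon genes passed over all genes, and 20 passed adjusted over the list alone. Astrocyte markers had a median of 0.03 beside them (adjusted p = 0.951). No single gene passed in limma (0 of 13722), with 681 at an unadjusted p under 0.05 where chance gives 686.1; voom on recovered reads called 15, all higher, and array weights 540. Leaving out replicate 1 of WT 2 h with amyloid-beta gave 1 call.

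In libraries labelled PD-1 KO at 2 h, 25 of 27 interferon genes were lower, with a median of -0.41. The list did not pass with an estimated correlation (adjusted p = 0.102), and 13 members passed adjusted over the list alone and 0 over all genes. Bst2 stood at -0.29 ± 0.18 (766 ± 35.9 against 948 ± 190, n = 3, adjusted p = 1). Homeostatic genes had 12 of 14 members lower (median -0.19, adjusted p = 0.148 with an estimated correlation). Of these, 3 passed adjusted over the list alone and 0 over all genes. Astrocyte markers had a median of 0.24 and oligodendrocyte markers of -0.34 beside them (adjusted p = 0.518 and 0.105 with an estimated correlation). No single gene passed in limma (0 of 13722), with 615 at an unadjusted p under 0.05; voom called 0 and array weights 120. Leaving out replicate 2 of PD-1 KO 2 h, or replicate 1 of its amyloid-beta group, gave 1 call.

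**Figure D2:**
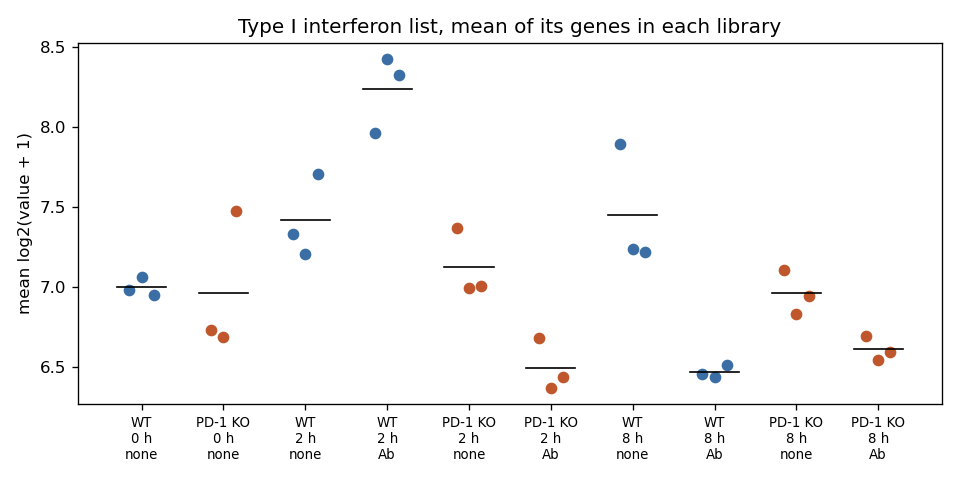
Mean log2(value + 1) of the type I interferon genes; each point is 1 of 3 libraries of a group and black bars are group means. At 2 h the WT libraries with amyloid-beta lie at 7.96 to 8.42, above 7.21 to 7.71 without, and the libraries labelled PD-1 KO with amyloid-beta lie at 6.37 to 6.68, below 6.99 to 7.37 without.

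The difference of the 2 h response between genotypes was tested as an interaction, since the series title asks what PD-1 does to the handling of amyloid. It passed for 7 genes, all lower in libraries labelled PD-1 KO relative to WT: Oas3 (-4.85 ± 0.74), Ifi27l2a (-2.64 ± 0.45), Zbp1 (-2.37 ± 0.45), Irf7 (-2.24 ± 0.35), Oasl2 (-2.06 ± 0.34), Ly6e (-1.70 ± 0.30) and Oas1a (-1.26 ± 0.25). Only 2 of them passed with voom (Irf7 and Oasl2) and 2 without trend (Irf7 and Oas3), while array weights called 477 genes, these 7 among them. Quantile normalization ended the calls of Zbp1 and Oas1a, and TMM factors and a fit of only the groups compared that of Oas1a. Oas3 lay at the floor in 1 library labelled PD-1 KO with amyloid-beta, so its fold depends in part on the floor. The whole interferon list had 27 of 27 members lower and a median of -1.42 (adjusted p = 0.00182 with an estimated correlation); 5 members passed over all genes and 22 adjusted over the list alone. In each genotype the 3 libraries with amyloid-beta did not overlap the 3 without in their mean interferon value (exact permutation p = 0.1 in each, the smallest that 3 against 3 allow). The phagocytic list was lower in 29 of 33 members with a median of -0.23, but not past the threshold with an estimated correlation (adjusted p = 0.203); 1 member passed adjusted over the list alone, and Trem2 (-0.02 ± 0.21) did not pass. The astrocyte list had a median of 0.20 (adjusted p = 0.168). The count was 30 without replicate 1 of WT 2 h with amyloid-beta, 22 without replicate 3 of WT 2 h and 15 without replicate 2 of PD-1 KO 2 h. It was 4 without replicate 2 of WT 2 h, replicate 3 of PD-1 KO 2 h, or replicate 2 or 3 of WT 2 h with amyloid-beta, 3 without replicate 1 of WT 2 h, and 2 without replicate 1 of PD-1 KO 2 h or replicate 2 of its amyloid-beta group. Irf7 and Oas3 kept their calls without any 1 library. Oasl2 lost its call without replicate 1 of PD-1 KO 2 h or replicate 2 of its amyloid-beta group, and Ifi27l2a without either of these or replicate 1 of WT 2 h. Zbp1 and Oas1a also lost theirs without replicate 1 of PD-1 KO 2 h with amyloid-beta (7 calls), and Zbp1 without its replicate 3 (10 calls). Ly6e, Zbp1 and Oas1a lost theirs without each library that left 4 calls or fewer.

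At 8 h the same question was asked of the later response. In WT, 281 genes fell and 18 rose with amyloid-beta, 3 libraries against 3. Of these 299, 92 also passed with quantile normalization, 96 with voom, 140 with pseudocount 10, 69 with the astrocyte score as covariate and 41 with only the groups compared. Pdgfra fell by -2.65 ± 0.37, Sox10 by -1.41 ± 0.20 (46.1 ± 9.98 against 123 ± 19.5) and Olig1 by -1.15 ± 0.22. Of the 11 oligodendrocyte lineage markers, 6 were lower and 5 higher; 4 fell past the threshold, also adjusted over the list alone, and 0 rose (median -0.25, adjusted p = 0.129 with an estimated correlation). Foxj1 fell by -1.91 ± 0.35, and the astrocyte markers Gfap by -1.35 ± 0.34 and Aqp4 by -1.27 ± 0.30. All 10 astrocyte markers were lower, 5 past the threshold and 8 adjusted over the list alone. Their median was -0.92 (adjusted p = 3.2e-08 at the preset correlation and 0.132 with an estimated one). Of 9 neuron markers 7 were lower and 2 higher, 2 lower past the threshold and 4 adjusted over the list alone (median -0.40, adjusted p = 0.132 with an estimated correlation). Fibroblast and vascular markers, 8 of 10 lower, did not pass as a list at the preset correlation (median -0.48, adjusted p = 0.115). Interferon genes fell in 12 of 27 cases and in 21 adjusted over the list alone (median -0.94, adjusted p = 0.0863 with an estimated correlation), with Ifit3 at -2.06 ± 0.31. Il1b fell by -1.58 ± 0.33 (20.3 ± 2.62 against 63.0 ± 9.04), C3 by -1.31 ± 0.23, Tlr2 by -0.63 ± 0.10 and Icam1 by -0.61 ± 0.11. The cytokine list did not pass at the preset correlation (adjusted p = 0.115), with 10 of 16 members lower and 6 higher. Of these, 2 were lower past the threshold, and 5 lower and 1 higher adjusted over the list alone. Cell cycle genes fell in 3 of 24 cases and in 11 adjusted over the list alone (median -0.44, adjusted p = 0.132 with an estimated correlation), with Ccna2 at -0.99 ± 0.17.

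The increases in WT at 8 h included the iron exporter Slc40a1 by 0.54 ± 0.10 (6085 ± 329 against 4231 ± 909) and Gclm by 0.49 ± 0.11. All 11 genes of the NRF2 oxidative stress list were higher, 1 past the threshold and 4 adjusted over the list alone (median 0.28, adjusted p = 0.132 with an estimated correlation). The same 11 of 11 were higher in the other 3 comparisons of amyloid-beta with none. The list did not pass there with an estimated correlation either (adjusted p = 0.356 in WT at 2 h, 0.182 in PD-1 KO at 2 h and 0.226 in PD-1 KO at 8 h). At the preset correlation it passed in all 4 comparisons (largest adjusted p = 0.000508, in PD-1 KO at 8 h). Cd36 (0.48 ± 0.14, adjusted p = 0.0732), Trem2 (-0.01 ± 0.15) and Apoe (-0.12 ± 0.18) did not pass. The phagocytic list had 1 member higher and 2 lower, 2 higher and 4 lower adjusted over the list alone, and did not pass (median -0.11, adjusted p = 0.124). Every library moved the total: it was 55 without replicate 1, 97 without replicate 2 and 513 without replicate 3 of WT 8 h, and 159, 102 and 177 without replicates 1, 2 and 3 of its amyloid-beta group. Gfap and Aqp4 lost their calls without replicate 1 or 2 of WT 8 h or replicate 1 or 2 of the amyloid-beta group, and Gfap without its replicate 3 too. Settings ended calls too: a fit of only the groups compared those of Pdgfra, Olig1, Gfap, Aqp4, Ccna2, Slc40a1 and Gclm, quantile normalization those of Il1b, Gfap and Aqp4, and voom those of Foxj1, Gfap and Aqp4. A fit without trend ended those of Gfap and Aqp4, and pseudocount 10 that of Gfap. With the astrocyte score Olig1, Foxj1 (-0.88), Gfap (-0.20) and Aqp4 (-0.34) did not pass, and C3 passed at -0.70. Gfap and Aqp4 are part of that score, so their loss follows largely by construction. Olig1 and Il1b lost theirs without replicate 1 of WT 8 h, and Gclm without replicate 1 or 2 of WT 8 h or replicate 2 or 3 with amyloid-beta.

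In libraries labelled PD-1 KO at 8 h, 8 genes fell and 0 rose with amyloid-beta by limma, with 1036 genes at an unadjusted p under 0.05; voom called 7 higher and 41 lower, and quantile normalization 6 and 38. The decreases included Cd52 by -0.93 ± 0.17 (1177 ± 101 against 2248 ± 196), Ms4a6c by -0.83 ± 0.14, Stap1 by -0.79 ± 0.15, Glrx by -0.74 ± 0.13, Ebi3 by -0.70 ± 0.14 and Ifngr1 by -0.54 ± 0.09. Pan-microglial genes were lower in 13 of 14 cases (median -0.35, adjusted p = 0.0828 with an estimated correlation), with 10 lower adjusted over the list alone and 0 over all genes. Oligodendrocyte markers fell as a list (10 of 11 lower, 2 adjusted over the list alone and 0 over all genes, median -0.42, adjusted p = 0.0302 with an estimated correlation), while astrocyte markers had a median of 0.14 (adjusted p = 0.457). The count was 0 without replicate 1 or 3 of PD-1 KO 8 h, or without any 1 of its 3 amyloid-beta libraries. It was 8 without replicate 2 of PD-1 KO 8 h (1 higher and 7 lower), of which 4 were among the original 8; Stap1 and Ebi3 lost their calls there. The fit without trend ended all 8 calls, TMM factors 3 with Stap1 and Ebi3 among them, and a fit of only the groups compared 2 with Ebi3 among them.

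The genotype difference of the 8 h response passed for 0 genes in limma, with 810 at an unadjusted p under 0.05; voom also called 0, and array weights 192. Cxcl10 (0.86 ± 0.36, adjusted p = 0.721) did not pass. The astrocyte list had 10 of 10 members higher (median 0.97, adjusted p = 0.327 with an estimated correlation), 8 of them past the threshold adjusted over the list alone, and the interferon list 23 of 27 (median 0.62, adjusted p = 0.568 with an estimated correlation), 6 of them so. Leaving out replicate 3 of WT 8 h gave 3 calls and replicate 1 of PD-1 KO 8 h with amyloid-beta gave 1.

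**Figure D3:**
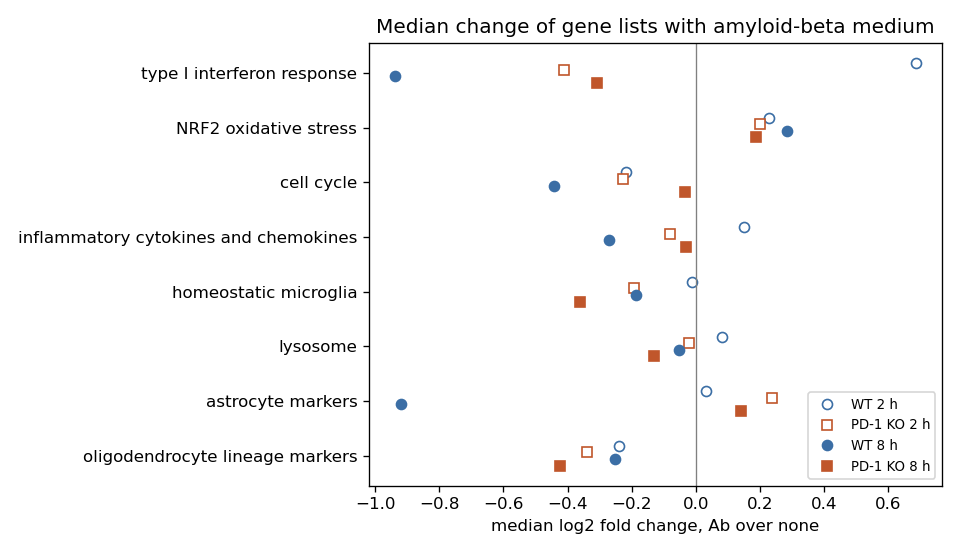
Median log2 fold change, amyloid-beta over none, of 8 gene lists in WT (blue circles) and libraries labelled PD-1 KO (orange squares), open at 2 h and filled at 8 h. The interferon medians are 0.69 in WT and -0.41 in PD-1 KO at 2 h, and -0.94 and -0.31 at 8 h.

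Between 2 h and 8 h the effect of amyloid-beta, averaged over genotypes, differed for 0 genes in limma, with 1042 at an unadjusted p under 0.05; voom also called 0, and array weights 532. The 8 h libraries carry title numbers of another series than those of 2 h, so time and library series cannot be told apart. Il1b came to -1.42 ± 0.33 (adjusted p = 0.174). Interferon genes had 27 of 27 members lower at 8 h than at 2 h (median -0.66, adjusted p = 0.0644 with an estimated correlation), 19 of them past the threshold adjusted over the list alone, and astrocyte markers 10 of 10 (median -0.48, adjusted p = 0.276 with an estimated correlation). The interferon medians went from 0.69 to -0.94 in WT, but from -0.41 to -0.31 in libraries labelled PD-1 KO. Those of the astrocyte markers went from 0.03 to -0.92 and from 0.24 to 0.14. Leaving out replicate 1 of WT 2 h with amyloid-beta, or replicate 2 or 3 of WT 8 h, gave 3 calls, and leaving out replicate 3 of PD-1 KO 2 h with amyloid-beta or of WT 8 h with amyloid-beta gave 1.

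Time in culture without amyloid-beta was followed as the background of these effects, with 6 libraries against 6 and folds averaged over the genotypes. The average can hide a difference of the genotypes in the effect of time. For 2 h against 0 h, exchanging the times of all WT libraries and of 1 pair labelled PD-1 KO called 827 genes, against 437 for the average. From 0 h to 2 h, 257 genes rose and 180 fell. Ptger4 rose by 1.23 ± 0.08 (527 ± 47.8 against 228 ± 48.7), Tnf by 0.97 ± 0.10 and Tlr2 by 0.62 ± 0.07. Cytip fell by 1.69 ± 0.15, Nr4a1 by 1.46 ± 0.22, Fos by 1.32 ± 0.11 and Dusp1 by 0.91 ± 0.11. Antigen presentation genes rose as a list (16 of 17 higher, 4 past the threshold and 8 adjusted over the list alone, median 0.25, adjusted p = 0.0317 with an estimated correlation), with Tap1 at 0.40 ± 0.08 and H2-K1 at 0.39 ± 0.08. Olig2 fell by 0.90 ± 0.15 beside them. The total was 257 without replicate 1 of PD-1 KO 2 h, 267, 283 and 287 without replicates 2 and 3 of WT 0 h and replicate 2 of PD-1 KO 0 h, and 290 without replicate 3 of PD-1 KO 2 h.

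From 0 h to 8 h, 584 genes rose and 674 fell. The 8 h libraries carry title numbers of another series than those of 0 h, so time and library series cannot be told apart here. NF-kB genes rose in 15 of 20 cases and in 19 adjusted over the list alone (median 0.75, adjusted p = 0.000409 with an estimated correlation), with Icam1 at 1.41 ± 0.08 and Nfkbiz at 1.20 ± 0.10. Cxcl2 rose by 2.76 ± 0.23 (352 ± 243 against 61.3 ± 57.1), Tnf by 1.74 ± 0.10 and Il1b by 1.62 ± 0.23. The cytokine list passed (9 higher and 1 lower of 16, 11 and 3 adjusted over the list alone, median 0.84, adjusted p = 0.0154 with an estimated correlation), though Ccl2, at the floor in 1 of the 6 libraries at 8 h, fell by 2.22 ± 0.34. Cell cycle genes fell (12 of 24, 21 adjusted over the list alone, median -0.64, adjusted p = 0.018 with an estimated correlation), with Rrm2 at -1.18 ± 0.21. So did cholesterol biosynthesis genes (8 of 19, 9 adjusted over the list alone, median -0.27, adjusted p = 0.0485 with an estimated correlation), and oligodendrocyte markers (3 of 11, 4 adjusted over the list alone, median -0.37, adjusted p = 0.0496 with an estimated correlation) with Olig2 at -0.89 ± 0.15.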

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

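The tests on the libraries' depth, on whole-label exchange and on a remaining transcript, those on single libraries, and that on astrocyte content for the interferon genes at 2 h were chosen after the result was seen; the estimated-correlation form of the single-library test was added after its preset form had been run.

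The response to amyloid-beta differed between genotypes at 2 h, by a test of the difference itself, for 7 genes: Oas3 (-4.85), Ifi27l2a (-2.64), Zbp1 (-2.37), Irf7 (-2.24), Oasl2 (-2.06), Ly6e (-1.70) and Oas1a (-1.26). It differed at the preset correlation for 8 lists, by their medians: type I interferon response (-1.42), pan-microglia and macrophage (-0.27), phagocytic receptors (-0.23), receptors of motility (-0.21), antigen presentation (-0.20, with a mean of 0.02), homeostatic microglia (-0.19), lysosome (-0.14) and the PD-1 axis (-0.0827). Of these, the interferon list alone passed with an estimated correlation (adjusted p = 0.00182).

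At 8 h the genotypes differed at the preset correlation for 9 lists: astrocyte markers (0.97), type I interferon response (0.62), cell cycle (0.48), alternative activation (-0.24), pan-microglia and macrophage (-0.15), disease-associated microglia (-0.13), homeostatic microglia (-0.13), phagocytic receptors (-0.11) and lysosome (-0.082). Between the times, 8 lists differed: type I interferon response (-0.66), astrocyte markers (-0.48), pan-microglia and macrophage (-0.26), inflammatory cytokines (-0.24), receptors of motility (-0.24), NF-kB pathway (-0.20), oligodendrocyte lineage markers (-0.15) and phagocytic receptors (-0.10). None of these 17 list calls passed with an estimated correlation. The difference between the times cannot be told apart from that between the library series.

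The genotype difference of the interferon response at 2 h did not rest on 1 library: without each of the 12 libraries in turn, the largest adjusted p of the list was 1.00e-30 at the preset correlation and 0.0188 with an estimated one. With the astrocyte score as covariate the median was -1.33, which argues against a change of astrocyte content with amyloid-beta as the whole source. The slope of the score came from libraries within groups, so it cannot show whether cultures richer in astrocytes respond differently. Only the difference between genotypes was followed in these ways. The decrease within libraries labelled PD-1 KO did not pass with an estimated correlation (adjusted p = 0.102). As many genes passed in 2 of 100 splits of the libraries, the real one included (real 7, highest other 9), a share under 0.05, though 1 other split called more. A response that depends on the labelled genotype may explain the pattern, as may anything else that differs between the 2 sets of cultures; neither was tested further, and the direction is tied to genotype labels that the Pdcd1 values leave open.

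Pdcd1 lay above the floor in libraries labelled PD-1 KO and at the floor in those labelled WT. Library depth is argued against by the scaled values. The deepest library labelled WT, with 48509985 reads, stood at the floor value of 1, which can hide up to 4 reads there. The shallowest labelled PD-1 KO, with 4648748 reads, stood at 8.19, from 4 reads. In 11 of the libraries labelled WT the floor hides no read. An exchange of all genotype labels may explain the pattern, since 15 of 15 libraries labelled PD-1 KO lie above the floor. A transcript left by the targeted allele, at a median value of 12.8, may explain the reads in these libraries. It would not by itself account for the floor in all 15 labelled WT. The gene-level values cannot tell these explanations apart, because they do not show exons.

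The decreases with amyloid-beta in WT at 8 h overlapped genes that mark the cultures labelled PD-1 KO. Of the 281 genes, 53.0% were higher in those libraries at 0 h, which share no library with the 8 h comparison, against 13.8% of all genes tested. With the astrocyte score as covariate, 28 of these 149 genes stayed called and their median went from -1.22 to -0.69 (median standard error from 0.28 to 0.24), which is consistent with a lower astrocyte content as a source. The score also ended most other calls (34 of 132 stayed), whose median moved less (-1.20 to -0.90) while their standard error rose (0.26 to 0.29). It does not account for the interferon genes, whose median stayed at -0.97. The count depended on single libraries, falling to 55 without replicate 1 of WT 8 h. It also fell to 97 without replicate 2 of WT 8 h and to 102 without replicate 2 of its amyloid-beta group. A loss therefore came without each of these libraries, and was largest without replicate 1 of WT 8 h. A group also loses power when a library is left out, which was not separated from the weight of that library.

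Other splits of the same libraries bear on the remaining counts. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; as many genes passed in 10 of them, by construction, for amyloid-beta in WT at 2 h (real 0, highest other 1098) and in PD-1 KO at 2 h (0 and 1), and in 1 for WT at 8 h (299 and 10), PD-1 KO at 8 h (8 and 0), and the genotypes at 0 h (2840 and 0), 2 h (4412 and 0), 2 h with amyloid-beta (5341 and 5), 8 h (3708 and 0) and 8 h with amyloid-beta (4626 and 0). The 1098 genes point to a structure of the WT libraries at 2 h that the treatment does not follow: replicates 2 and 3 without and replicate 1 with amyloid-beta stood against the other 3, with 68 of 79 ribosomal protein genes higher in the former (median 0.43). Among 100 splits, as many genes passed in 1 for the genotypes over all conditions (8158 and 5083), in 2 for 2 h against 0 h (437 and 827) and in 1 for 8 h against 0 h (1258 and 484), each a share under 0.05. The split with 5083 genes left the genotypes at 2 h, at 2 h with amyloid-beta and at 8 h with amyloid-beta as labelled. That with 827 exchanged the times of all 6 WT libraries and of 1 pair labelled PD-1 KO, and so followed mainly a difference of the genotypes in the effect of time. For the genotype difference at 8 h (100 of 100; 0 and 135) and the time difference (100 of 100; 0 and 5) the real count is 0, so every split is as large by construction and the splits say nothing about chance. The split with 135 exchanged all 3 WT pairs and 1 pair labelled PD-1 KO, and so lay close to the effect of amyloid-beta over both genotypes.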

How the results depend on the processing

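Of 320 pairs of a named gene and a comparison, 220 passed the threshold. Of these, 165 kept direction and threshold under every alternative that was run for them. Of the 100 that did not pass, 66 never did in any run. The astrocyte score was run for 144 of the 320 pairs, those on the effect of amyloid-beta. It was not run for PD-1 KO against WT or for time without amyloid-beta. Of 136 list calls, 12 stayed with an estimated correlation, and fry dropped 60. A low-value filter of 50, no filter, pseudocount 0 and robust empirical Bayes moved no count by over 1.5 times. In every change below the cause was not tested, except that a fold minimum lowers counts by construction.

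For amyloid-beta in WT at 8 h (299 genes), the count was 141 with pseudocount 10, 98 with quantile normalization, 68 with only the groups compared, 1762 with array weights, 106 with voom and 199 with a log2 fold of 1 or more. For PD-1 KO at 8 h (8 genes) it was 44 with quantile normalization, 5 with TMM factors, 14 with only the groups compared, 0 without trend by limma, 459 with array weights, 48 with voom, 27 with the astrocyte score and 2 with the fold minimum. At 2 h (0 genes each) array weights gave 540 in WT and 120 in PD-1 KO, and voom 15 in WT. The genotype difference at 2 h (7 genes) gave 2 without trend, 477 with array weights and 2 with voom; that at 8 h (0 genes) gave 5 with only the groups compared and 192 with array weights. The time difference (0 genes) gave 1 with only the groups compared, 532 with array weights and 26 with the astrocyte score. A pair chosen after the data were seen, replicate 1 of WT 2 h with amyloid-beta and replicate 3 of WT 8 h, was also left out. The counts were then 623 for WT at 8 h and 23 for PD-1 KO at 8 h. They were 29 and 16 for the genotype differences at 2 h and 8 h, and 6 for the time difference. Correlations with the other libraries of the group were 0.977 and 0.980 for the first and 0.976 and 0.980 for the second. Replicate 1 of PD-1 KO 0 h stood as far from its group, at 0.977 and 0.975. The lowest correlation of any pair within a group, 0.969, was that of replicates 2 and 3 of PD-1 KO 2 h with amyloid-beta, which were kept. Without this replicate 2 the genotype difference at 2 h gave 2 genes, and without this replicate 3 it gave 10. Between genotypes, array weights gave 6749 at 2 h; the fold minimum gave 1292 at 0 h, 1806 at 2 h, 2245 at 2 h with amyloid-beta, 1835 at 8 h, 2319 at 8 h with amyloid-beta and 1968 over all conditions. From 0 h to 2 h the count was 250 with only the groups compared, 1836 with array weights and 37 with the fold minimum, and from 0 h to 8 h 2347 and 159. The voom, astrocyte score and left-out pair settings were chosen after the data were seen.

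Some directions turned, for lists that of the list test, whether or not the median changed sign. With quantile normalization, the test of disease-associated microglia genes turned at medians of 0 in the genotype difference at 8 h, 0.00 between genotypes at 2 h (0.003623) and -0.03 (-0.0306) at 2 h with amyloid-beta, and over all conditions P2ry12 was -0.15 and Tmem119 -0.16. With the astrocyte score, medians of the genotype difference at 8 h were 0.07 for pan-microglia (0.0735), 0.04 for disease-associated microglia (0.0381), -0.03 for alternative activation (-0.0321), 0.07 for phagocytic receptors (0.0694) and 0.07 for lysosome (0.0733).

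Leaving out 1 library in turn gave 55 to 513 genes for WT at 8 h, 0 to 8 for PD-1 KO at 8 h, 0 to 1 for each genotype at 2 h, 2 to 30 and 0 to 3 for the genotype differences at 2 h and 8 h, 0 to 3 for the time difference, and 257 to 598 from 0 h to 2 h. No paired analysis was possible because the titles carry no replicate numbers or mark of a shared animal, litter or day; the numbers used here follow only the order of the accessions. The edgeR and DESeq2 alternatives were not run, since the floor hides up to 4 reads per value and whole reads were therefore not recovered for every gene.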

Other observations

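The tests of gene positions were chosen after the genes lower in libraries labelled PD-1 KO had been seen, with their predictions written before they ran; the share of windows was added afterwards.

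Of the genes placed on GRCm38, 1228 had no overlap between the 15 libraries labelled PD-1 KO and the 15 labelled WT, 1042 higher and 186 lower. Within 10 Mb of Pdcd1, 18 of 89 genes were among them (20.2%) against 8.95% of the other genes, a ratio of 2.26 (Fisher's exact p = 0.00108, two-sided, which treats genes as independent). Of 13586 windows centred on a gene, 1.82% held a share as high. The 18 genes near Pdcd1 were 15 higher and 3 lower, a mix much like the 1042 higher and 186 lower of all 1228. A segment of chromosome around Pdcd1 that differs between the 2 sets of mice may contribute, though neighbouring genes that are regulated together would give the same picture.

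Of the 35 genes that were lower without overlap by a log2 fold of 1 or more, the fullest window of 10 Mb, on chromosome 11 from 110000001 to 120000000, held 6 (Cd300lb, Cd300ld, Nat9, Tmem104, Mettl23 and Slc26a11). In 1000 shuffles of positions the 95th percentile was 3 and the highest 4. Other such genes lie close together elsewhere, such as Cd5l and Fcrl1 on chromosome 3 and Dynlt1b and Tmem181b-ps on chromosome 17. Segments from another strain may be a source of part of the genotype differences, Olfml3 (-4.18) among the candidates; Cd300lb and Cd300ld belong to 1 gene family, so shared regulation remains open, and no sequence was available to test the strain.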
